A study of Mus musculus with 2 samples.

How the data were processed

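Single-cell RNA-seq data were used, 1 library from a control host and 1 from a Plexin-B2 conditional knockout (cKO) host, both from mouse brain that had received intracranial KR158 glioblastoma cells. Per the labels' protocols, brain tissue around the injection site was dissociated with papain, debris was removed by Percoll centrifugation, red blood cells were lysed, and droplet libraries were made with a 10x Genomics 3′ kit. No sort for immune or tumour cells is described in these protocols.

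The deposited matrices hold raw UMI counts per gene and barcode, made with Cell Ranger 7.1.0 per the file headers and the submitters' processing notes, on genome build mm10 per those notes. A UMI count is the number of distinct tagged RNA molecules. The annotation release and whether intronic reads were counted are not given in the sources used here. The deposited control matrix holds 10942 barcodes, each with at least 500 UMIs, and so was already filtered. The deposited cKO matrix holds 2377349 barcodes, of which 1513730 have a UMI, and so was not filtered. Both files list the same 32285 genes. Of their gene identifiers, 99.6% are in GENCODE vM21, which was used for coordinates on the same build.

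The same filters were set on both libraries: at least 1000 UMIs, at least 500 genes, at most 10% mitochondrial UMIs, and no doublet call by Scrublet run per library with an expected share of 6%. Scrublet, run in scanpy 1.11.5, called 5.21% of control and 3.48% of cKO cells. Kept cells of both libraries were clustered together on log counts per 10000, with 2000 variable genes (mitochondrial genes, Xist, Tsix and 4 Y-linked genes excluded), 30 principal components, 15 neighbours, a shared-neighbour graph and Leiden resolution 1.0 (leidenalg 0.10.2). No batch integration was used. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used for the other steps.

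Clusters were named from 21 marker sets fixed before the data were examined. A marker counted as detected in at least 10% of a cluster's cells and at a level at least 2-fold over the mean of the other clusters, and at least 3 detected markers were needed. A cluster stayed unnamed if its top 10 genes held more markers of another class, or if its median UMI count was under 1/3 of its own sample's with no own marker among those genes. A cluster with at least 75% of the markers of a second class also stayed unnamed; that rule was set after the data were seen. It left out clusters 19 and 32, which held 0.981% and 0.235% of control cells and 1.52% and 0.0768% of cKO cells.

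UMIs were summed per class and library and expressed as CPM, UMI counts scaled to a total of 1e6 in that sum. The log2 ratio is cKO over control, with an exact conditional (Clopper-Pearson) 95% interval. CPM values carry exact Poisson intervals, and shares of cells carry exact Clopper-Pearson intervals. All intervals cover counting error only. With 1 library per group no test between groups is possible, and no p-value or count of changed genes is given. Classes were compared with at least 100 cells in both libraries. For shares of cells with a UMI, each cell was also thinned to 1000 UMIs; every kept cell reached that depth.

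The named genes follow a rule fixed before the data were examined. In microglia, the rule takes Plxnb2, the 8 highest and 8 lowest ratios among genes with at least 50 CPM and 30 UMIs in one of the libraries, and up to 4 members of each of 21 gene lists with the highest absolute ratios. In the other classes it takes the 3 highest and 3 lowest ratios. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, Gm and Rik genes and Xist, Tsix, Ddx3y, Uty, Eif2s3y and Kdm5d were left out of the highest and lowest ratios. Monocytes or macrophages and tumour cells were also planned as main classes, but no cluster received either name. A gene list and a gene that the rule names are not reported here.

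A list's median log2 ratio was taken over members with at least 20 CPM on average, for lists with at least 3 such members. Its interval comes from order statistics and is the full range for lists of 8 or fewer measured members. The percentile places the median among 10000 random lists of the same size matched on mean expression and describes these libraries alone. A member counted as higher or lower at 1.5-fold or more with an interval excluding equality.

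The ratio and list steps were tested on simulated microglia sums over 6373 genes, of which 200 were changed. Those sums were Poisson counts without variation between cells or animals, so the coverage below holds for counting error alone. For simulated log2 ratios of 1, -1, 2 and -2, the median recovered was 0.96, -1.02, 1.98 and -2.06, and the interval held the true value for 98.0%, 98.0%, 90.0% and 100.0% of 50 genes each. A changed list of 10 genes reached percentile 100.0 and an unchanged list of 18 genes percentile 43.8.

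Alternatives set before the data were examined were other UMI floors, mitochondrial limits and Leiden resolutions, no doublet removal, a relative UMI floor for the unfiltered library, TMM factors (edgeR 4.0.16), CPM without mitochondrial and ribosomal protein genes, the mean of per-cell CPM, and other expression floors for lists. Thinned cells, the union of all microglia-marked clusters and class shares at a mitochondrial limit of 5% were added after the data were seen. Free RNA was not subtracted, since the control matrix holds no empty droplets.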

Results

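The series asked how loss of Plexin-B2, a receptor for class 4 semaphorins, in Cx3cr1-expressing myeloid cells alters brain that carries a glioblastoma graft. Host mice received KR158 cells, a mouse glioblastoma line, by intracranial injection. Tamoxifen at 100 mg/kg was given from 3 days before the injection until 8 weeks after it, to activate a Cre recombinase driven from the Cx3cr1 locus. The control host carried 1 floxed Plxnb2 allele, so it is a heterozygote rather than a wild type, and the cKO host carried 2. There was 1 library per genotype. Differences therefore have no replicate check, and genotype, animal and library preparation cannot be separated.

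The control matrix held 64756949 UMIs in 10942 barcodes, and the cKO matrix 63785513 UMIs, of which 20.6% lay in barcodes with under 500 UMIs. Filtering kept 7648 control and 5210 cKO cells. In microglia the median depth was 3941 UMIs per cell in the control and 6102 in the cKO library.

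Astrocytes, microglia, oligodendrocytes and endothelial cells made up most of both libraries. Microglia-like cells were 16.9% of control cells (1290 cells, 16.0 to 17.7) and 10.8% of cKO cells (565 cells, 10.0 to 11.7). Endothelial-like cells were 9.09% (8.45 to 9.75) and 17.0% (16.0 to 18.1), and neuroblast-like cells 2.92% (2.55 to 3.32) and 6.53% (5.87 to 7.23). Astrocyte-like cells were 34.4% (33.4 to 35.5) and 29.3% (28.1 to 30.6). Oligodendrocyte-like cells were 12.3% (11.5 to 13.01) and 10.8% (9.94 to 11.6), pericyte-like or smooth-muscle-like cells 2.16% (1.84 to 2.51) and 3.34% (2.87 to 3.86), and ependymal-like cells 3.16% (2.78 to 3.58) and 2.13% (1.76 to 2.56). Choroid plexus-like cells were 4.60% of control cells (352 cells) and 0.0768% of cKO cells (4 cells). The control matrix was filtered before deposit and the cKO matrix was not, which can shift these shares. With a relative UMI floor for the cKO library, the oligodendrocyte and pericyte differences changed sign. With a mitochondrial limit of 5%, the microglial difference of -6.02 percentage points was -12.4, the oligodendrocyte difference of -1.48 was -0.46 and the ependymal difference of -1.03 was -0.41. The endothelial difference of 7.92 was 12.1 at Leiden resolution 0.5. The astrocyte difference of -5.11 percentage points was -1.15 with a mitochondrial limit of 20%, and the neuroblast difference of 3.61 was 0.811 with a floor of 2000 UMIs.

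**Figure D1:**
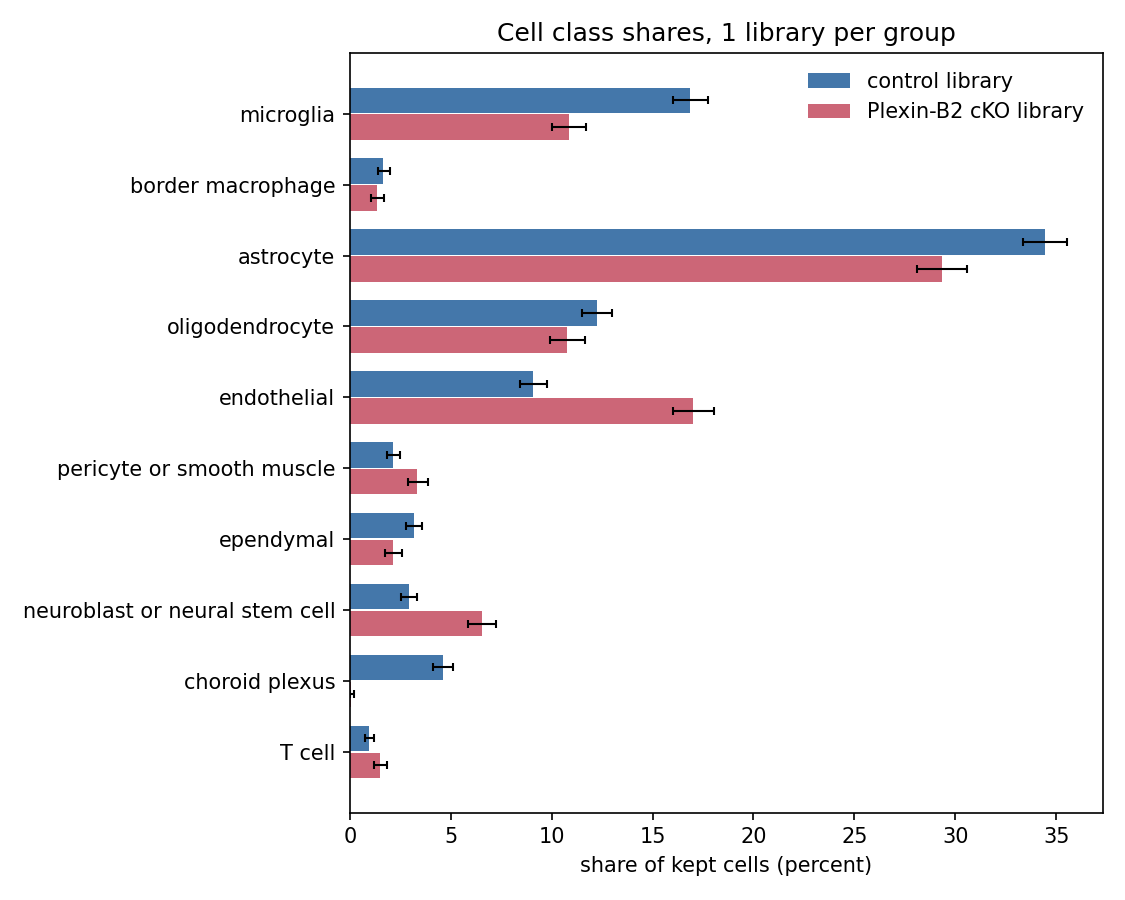
Share of kept cells (percent, horizontal axis) in each named class for the control library and the Plexin-B2 cKO library, with exact binomial intervals for counting error. Endothelial-like cells stand at 9.09% and 17.0%, and choroid plexus-like cells at 4.60% and 0.0768%.

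No cluster met the naming rule for tumour cells or for monocytes or macrophages under the settings run. Cells with at least 4 of the 8 tumour markers numbered 4 of 7648 in the control and 0 of 5210 in the cKO library, and tumour cells with fewer of these markers detected are not counted. Cells with at least 6 of the 12 monocyte or macrophage markers numbered 1 and 4. Cluster 23, whose best-scoring class was tumour cell, had only 1 marker of that set detected and stayed unnamed. It held 98 control and 24 cKO cells. Tumour cells and infiltrating monocytes were thus not identified as a class in either library and could not be compared here. Border macrophage-like cells, resident at the brain's surfaces and vessels, were 1.66% of control cells (127 cells) and 1.32% of cKO cells (69 cells), too few for a full comparison. A further 3 clusters carried microglial markers but stayed outside the named class. Clusters 7 and 14 had low UMI counts and held 4.77% and 1.46% of control cells and 2.96% and 3.45% of cKO cells. The cycling cluster 25, with Cdkn2a of the tumour naming set among its top 10 genes, held 0.0262% and 0.979%. Cluster 8, with endothelial and pericyte markers, also stayed unnamed and held 2.01% and 6.22%, so the endothelial shares leave it out. With clusters 7, 14 and 25, microglia-marked cells numbered 1769 and 950, or 23.1% of control and 18.2% of cKO cells.

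Plxnb2 (ENSMUSG00000036606, mm10 chromosome 15, 89155549 to 89180788, minus strand, protein-coding) was lower in cKO microglia. Its level was 200.8 CPM in the control (1120 UMIs, 189 to 213) and 38.6 CPM in the cKO library (155 UMIs, 32.8 to 45.2), a 5.20-fold difference (4.39 to 6.19). After thinning, 17.4% of control and 3.36% of cKO microglia had a Plxnb2 UMI, against 52.4% and 21.9% without thinning. In oligodendrocyte-like cells, where the gene was near background, the thinned shares were 0.534% and 0.178% at median depths of 6396 and 7585 UMIs. Border macrophage-like cells had 101 and 32.3 CPM (log2 ratio -1.65, -2.68 to -0.74, from 60 and 12 UMIs). Ependymal-like cells had 254 and 265 CPM (log2 ratio 0.06, -0.07 to 0.19), and astrocyte-like cells 33.0 and 38.6 CPM (0.23, 0.01 to 0.44), which became -0.17 after thinning. The intervals for endothelial-like, oligodendrocyte-like, pericyte-like and neuroblast-like cells included 0. A 3′ tag may lie outside the deleted part of the gene, so these counts do not measure recombination.

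**Figure D2:**
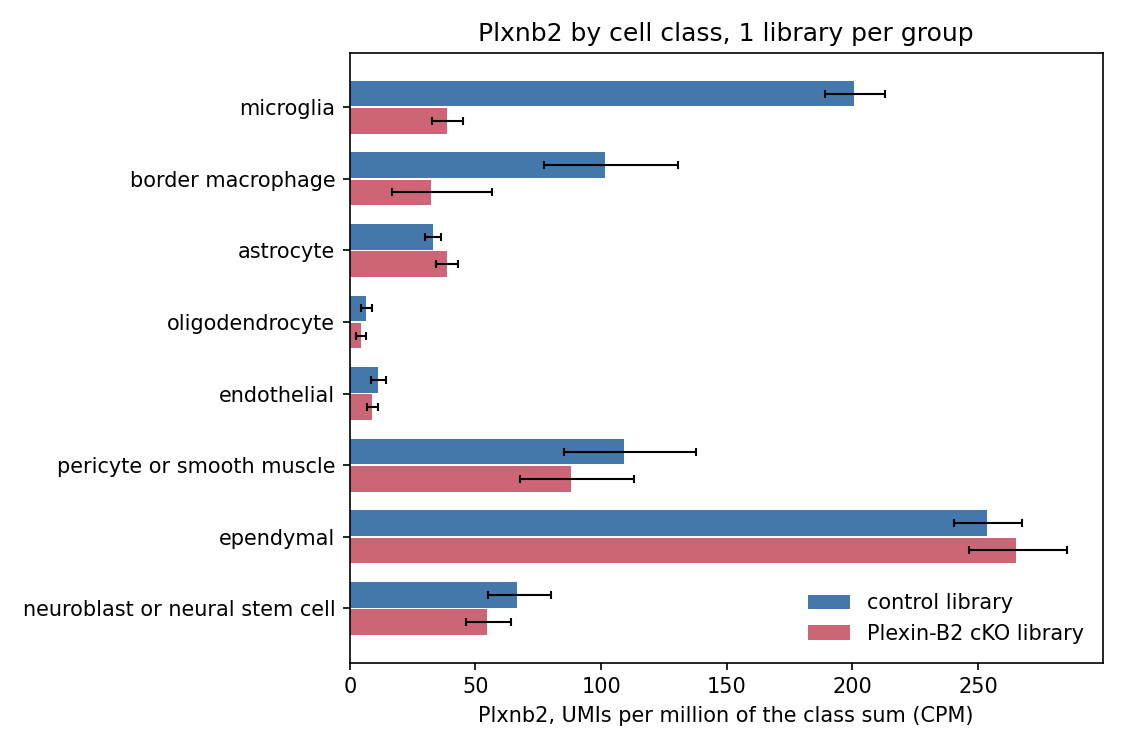
Plxnb2 level (CPM of the class UMI sum, horizontal axis) by cell class in the control library and the Plexin-B2 cKO library, with exact Poisson intervals. Microglia stand at 200.8 and 38.6 CPM, and ependymal-like cells at 254 and 265 CPM.

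Among genes that passed the expression minimum, the highest ratio in microglia was that of Cdkn1a, which encodes the cell cycle inhibitor p21 (mm10 chromosome 17, 29090976 to 29100727). It stood at 20.6 CPM in the control and 698 CPM in the cKO library (log2 ratio 5.08, 4.81 to 5.36). After thinning, 1.47% of control and 37.3% of cKO microglia had a Cdkn1a UMI, against 5.97% and 68.0% without thinning, while oligodendrocyte-like cells had 1.92% and 1.43% after thinning. Gdf15, a stress-induced cytokine of the TGF-beta family, was higher (log2 ratio 3.51, 3.21 to 3.84), as were the interferon-induced genes Ifi27l2a (3.20, 3.02 to 3.38), Slfn5 (2.48, 2.05 to 2.94) and Ifit3 (2.38, 2.01 to 2.78) and the chemokine gene Ccl5 (2.99, 2.55 to 3.45). Ccl5 had a UMI in only 15 control and 30 cKO microglia (1.16% and 5.31%), and is also among the top 10 genes of the T cell cluster. Gdf15 had a UMI in 31 and 72 (2.40% and 12.7%). The ratios of Cxcl9 (4.87) and Gpnmb (4.74) rest on 2 cKO cells each. With a floor of 2000 UMIs the Gpnmb ratio became -3.22.

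Among the lowest ratios in microglia, Ttr, the transthyretin gene of the choroid plexus, stood at 1542 CPM in the control and 1.25 CPM in the cKO library (log2 ratio -10.27, -11.90 to -9.05). It was also at 1393 CPM in control astrocyte-like and 1114 CPM in control oligodendrocyte-like cells, next to the higher choroid plexus share of that library. Enpp2, also abundant in choroid plexus, had a log2 ratio of -2.48 (-2.85 to -2.14). The others were Ccdc30 (-1.48), Lars2 (-1.35), Csmd3 (-1.10), Car2 (-1.10) and the heat-shock gene Hspa1b (-1.09). Reads of rRNA-like gene models made up 3.25% of control and 1.46% of cKO microglial UMIs. This difference was not particular to microglia. The shares were 3.89% and 1.80% in astrocyte-like, 3.23% and 1.52% in endothelial-like and 3.01% and 1.42% in all kept cells.

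Interferon response genes were higher together in cKO microglia. All 14 measured members were higher, with a median log2 ratio of 2.25 (1.35 to 2.48), at percentile 100.0 of matched random lists. Oasl2, an antiviral oligoadenylate synthetase-like gene, had a log2 ratio of 3.32 (2.73 to 3.97). Of 15 inflammatory cytokine and chemokine genes, 12 were higher and 3 were neither (median 1.38, 0.79 to 2.03, percentile 100.0). The 12 include Cxcl9, which rests on 2 cKO cells, and Ccl5, with a UMI in 5.31% of cKO microglia. Il1b had a log2 ratio of 2.22 (1.89 to 2.56) and Ccl12 of 2.03 (1.90 to 2.17). Of 10 class I antigen presentation genes, 6 were higher and 4 neither (median 0.68, 0.17 to 1.44, percentile 100.0), with H2-Q7 at 2.01, Tap1 at 1.44 and H2-D1 at 0.95. For class II genes the median was 0.43 (-0.04 to 0.67) with 1 of 5 members higher, Cd74 at 0.67, which became -0.61 with a floor of 2000 UMIs.

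**Figure D3:**
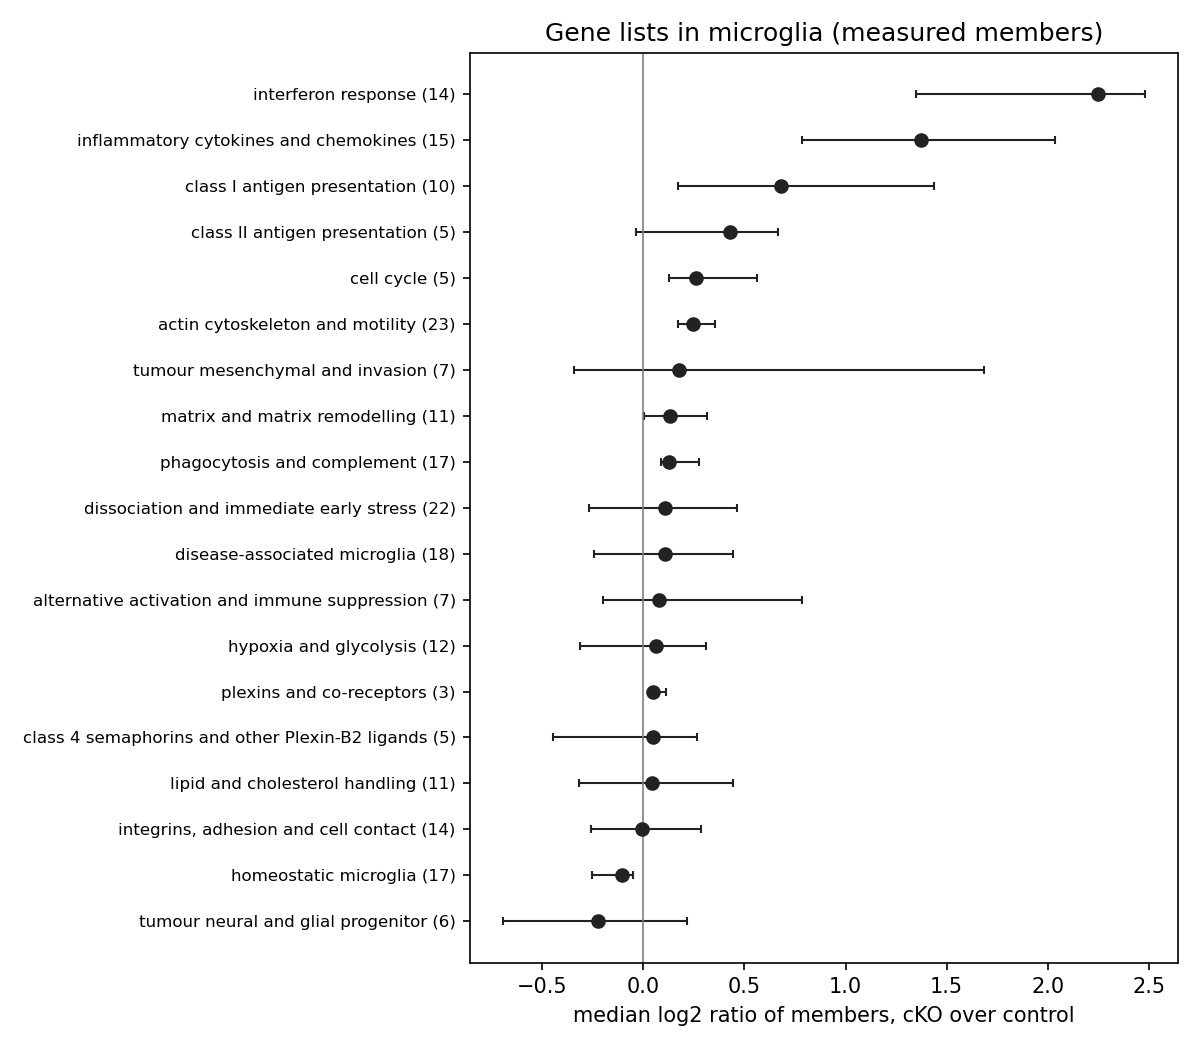
Median log2 ratio of each gene list in microglia, cKO over control (horizontal axis), with order-statistic intervals; the number of measured members is in parentheses, and 1 list is not shown. The interferon response list stands at 2.25 and the homeostatic list at -0.11.

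Homeostatic microglial genes differed little as a group. Of 17 members, 1 was lower and 16 neither (median -0.11, -0.25 to -0.05, percentile 0.070). The lower member was Cx3cr1, the fractalkine receptor gene whose locus carries the Cre (mm10 chromosome 9, 119901616 to 120069879), at 4863 and 2313 CPM (log2 ratio -1.07, -1.11 to -1.04). Gpr34 stood at -0.44 and the growth factor receptor gene Csf1r at -0.43. Of 18 disease-associated microglial genes, 4 were higher and 14 neither (median 0.10, -0.24 to 0.44, percentile 63.8). The 4 were Cst7 (2.32), Axl (1.54), Csf1 (1.39) and Gpnmb, which rests on 2 cKO cells as given above.

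Of 23 actin cytoskeleton genes, 2 were higher, Tmsb10 (1.28) and Actg1 (0.70), with a median of 0.25 (0.17 to 0.35, percentile 99.99). The actin median was also positive elsewhere, at 0.16 in endothelial-like, 0.14 in oligodendrocyte-like and 0.14 in neuroblast-like cells. It was 0.11 in astrocyte-like, 0.11 in ependymal-like and 0.09 in pericyte-like or smooth-muscle-like cells. Percentiles in these classes ran from 93.4 to 99.9, so the shift was not particular to microglia. Dissociation and immediate early stress genes went both ways, with 5 of 22 higher and 4 lower (median 0.11, percentile 75.7). Atf3 stood at 1.12 and Klf2 at -0.94. No measured member passed the rule among 3 plexins and co-receptors (median 0.05) or 5 genes of class 4 semaphorins and other Plexin-B2 ligands (0.05). The same held for 12 hypoxia and glycolysis genes (0.06), 11 lipid genes (0.04) and 5 cell cycle genes (0.26). That cell cycle result leaves out the unnamed cycling cluster and became -0.094 after thinning. Over all microglia-marked clusters, which include the cycling cluster, the cell cycle median was 3.43, with 9 of 11 measured members higher. For matrix genes the median was 0.13, with Mmp2, a gelatinase gene, at 1.69 (1.31 to 2.07) as the 1 higher member of 11. For integrins and adhesion it was -0.01, with Vcam1 (0.93) and Icam1 (0.83) higher among 14. For phagocytosis and complement genes it was 0.13, with Axl and Gas6 (0.82) higher among 17, and for alternative activation 0.08, with Tgm2 (0.79) higher among 7. In the tumour mesenchymal list (median 0.18) the higher member was also Mmp2, and in the tumour progenitor list (-0.22) Ptprz1 (-0.70) and S100b (-0.59), both glial transcripts, were lower. The T cell list had under 3 measured members in microglia.

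Interferon genes were also higher in other cKO classes, counted over the measured members of the 22 listed, with the same limit of the expression minimum. The list median was 2.60 in ependymal-like cells (11 of 11 members higher), 2.09 in astrocyte-like cells (10 of 10), 1.31 in pericyte-like or smooth-muscle-like cells (8 of 8), 1.25 in oligodendrocyte-like cells (2 of 3) and 0.92 in endothelial-like cells (15 of 17). The highest ratios included Ifit1 in ependymal-like cells (log2 ratio 4.40, 3.95 to 4.88), the chemokine gene Cxcl10 in astrocyte-like cells (3.74, 3.33 to 4.19, with a UMI in 1.64% of cKO cells), Ifi27l2a in oligodendrocyte-like cells (3.74, 3.35 to 4.15) and Ifi27 in neuroblast-like cells (2.13, 1.83 to 2.43). Lcn2, an acute-phase gene, led in endothelial-like cells (3.08, 2.79 to 3.39). The class I list median was 1.63 in ependymal-like cells (4 of 6 members higher) and 0.96 in pericyte-like or smooth-muscle-like cells (6 of 7). It was 0.37 in astrocyte-like (1 of 5), 0.36 in endothelial-like (1 of 10) and 0.33 in oligodendrocyte-like cells (1 of 4). In neuroblast-like cells it was -0.31, with no member of 3 higher. Cdkn1a had log2 ratios of 0.54 in astrocyte-like, 0.45 in oligodendrocyte-like and 0.19 in endothelial-like cells, and of 3.58 (2.89 to 4.36) in border macrophage-like cells.

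**Figure D4:**
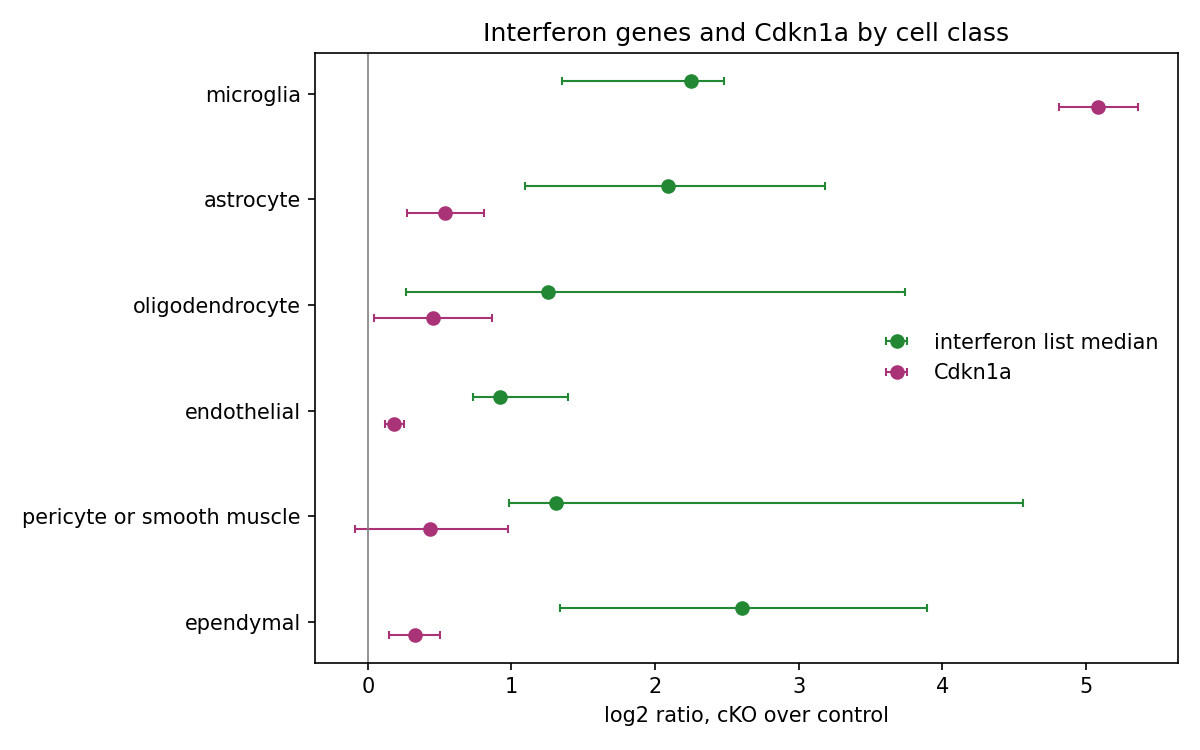
Log2 ratio, cKO over control (horizontal axis), of the interferon list median with order-statistic intervals and of Cdkn1a with exact counting intervals, by cell class. The interferon median is 2.25 in microglia and 2.09 in astrocyte-like cells, while Cdkn1a stands at 5.08 and 0.54.

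Stress genes had a median of 0.88 in ependymal-like cells (12 of 19 higher) and -0.43 in endothelial-like cells (1 of 20 higher, 3 lower). In pericyte-like or smooth-muscle-like cells the class II genes H2-Ab1 (log2 ratio 7.27, 4.77 to 12.58), Cd74 (6.27, 4.70 to 8.56) and H2-Aa (6.14, 3.61 to 11.46) had the highest ratios. These rest on 1, 3 and 1 control UMIs, and H2-Ab1 had a UMI in 18 of 174 cKO cells. In that class Thbs1 (-2.79) was low, from 15 control cells with a UMI. In astrocyte-like cells the low ratio of Mgp (-4.18) came from 25 control cells and became 0.71 with a floor of 2000 UMIs. The microglial transcripts C1qc (-1.30) and Ctss (-1.23) were lower in cKO oligodendrocyte-like cells, next to the lower microglial share of that library.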

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

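The tests on homeostatic genes, on dissociation stress and on a subset of cKO cells alone were chosen only after the results were seen. With 1 library per genotype, a biological effect of the genotype and any difference between animals or preparations stay open for each pattern here.

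In the cKO library, barcodes with 1 to 100 UMIs carried hepatocyte transcripts that its cells nearly lack, a signal in data outside the comparisons. Alb made up 0.353% of UMIs in those barcodes and Apoa2 0.185%, against 22 and 45 UMIs in all kept cells; the control matrix holds no such barcodes.

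A cycling cluster with microglial markers, kept out of the comparisons because it is unnamed, held 51 cKO cells and 2 control cells, and its Mki67 level in the cKO library was 876 CPM. Its top 10 genes held Cdkn2a, a tumour marker of the naming sets, and no microglial marker, so the naming rule left it unnamed. All 10 microglial markers were detected in it. No kept cKO cell of any cluster had over 3 of the 8 tumour markers. Whether the cycling cluster holds tumour cells was not tested. It is nearly a single-library cluster. Over all microglia-marked cells, Mki67 had 15 UMIs in the control and 452 in the cKO library.

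Interferon genes were higher in cKO microglia, with a median log2 ratio of 2.25. A difference across the whole library met its prediction, since the lowest interferon median of astrocyte-like, oligodendrocyte-like and endothelial-like cells was 0.92, though the oligodendrocyte value rests on 3 genes. A subset of cells stays open: without the 10% of cells of each library with the highest interferon share the median was 2.82, a step that also drops control cells by the measured outcome, and without such cells of the cKO library alone it was 1.32 (0.93 to 1.996), a range that includes the bound of 1.12 set for that test. Dissociation stress stays open, since the stress list median in microglia was 0.11 with 5 of 22 members higher and 4 lower, while it was 0.88 in ependymal-like (interferon median 2.60), 0.44 in neuroblast-like, 0.17 in pericyte-like (interferon 1.31), 0.13 in oligodendrocyte-like (interferon 1.25), -0.11 in astrocyte-like (interferon 2.09) and -0.43 in endothelial-like cells (interferon 0.92). The pattern may be a response of the whole tissue or of the preparation, and these data do not separate that from a response of Plxnb2-deficient cells.

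Cdkn1a was higher in cKO microglia, with a log2 ratio of 5.08. A difference across the whole library would need similar ratios elsewhere, but the highest of astrocyte-like, oligodendrocyte-like and endothelial-like cells was 0.54. Border macrophage-like cells, where Cdkn1a was also higher, and the small immune classes were not part of that test. A small subset was not the source, since 37.3% of thinned cKO microglia had a UMI. Activity of p53 target genes is a candidate explanation: the other p53 targets had a median log2 ratio of 0.95 (-0.16 to 1.13) at percentile 100.0 of matched lists, with Phlda3 at 4.02 and Bax at 1.39, while 6 of 15 measured targets passed no rule. What would activate them, such as the recombination, the genotype or the individual animal, was not tested.

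Cx3cr1 was lower in cKO microglia, with a log2 ratio of -1.07. After thinning the ratio was -1.02, as the prediction for no depth effect required. Thinning keeps each gene's expected share of UMIs, and CPM already divides by depth, so that test cannot decide on depth. A general loss of homeostatic expression was not matched, since the other 16 homeostatic genes had a median of -0.11. A difference in Cx3cr1 allele dose could not be told apart from other causes. Border macrophage-like cells had a ratio of -0.62 (-0.90 to -0.34), between the bounds set for that test. Clusters 7 and 14 had -1.31 and -2.15. As point values both lie below the range set for allele dose, which does not cover every dose difference. Both clusters had low UMI counts. The labels give both hosts 1 Cre allele at this locus.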

How the results depend on the processing

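The thinned cells, the union of microglia-marked clusters and the shares at a mitochondrial limit of 5% were chosen after the data were seen. No paired analysis was possible because each genotype has 1 library. In microglia, the log2 ratio of Plxnb2 stayed between -2.57 and -2.29, of Cdkn1a between 5.02 and 5.22 and of Cx3cr1 between -1.19 and -1.02 over the alternatives run, and the interferon median between 2.12 and 2.39. The microglial share difference (cKO minus control) was -12.4 percentage points with a mitochondrial limit of 5% and between -6.38 and -5.19 over the other settings run for shares. These settings do not include the union of microglia-marked clusters, which made up 23.1% of control and 18.2% of cKO cells. Of 842 alternative values of gene ratios 824 kept their direction, of 308 list medians 287, and of 72 share differences 70. Some of these alternatives could hardly change a sign. TMM factors shift all log2 ratios of a class by 1 amount, at most 0.077, and all 127 gene ratios kept their direction. Leaving out mitochondrial and ribosomal protein genes is also a constant shift per class, and all 128 kept it. Many of these genes were named for high absolute ratios in these same data. The cause of the changes below was not tested.

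A mitochondrial limit of 5% left 3987 control and 3085 cKO cells, and share differences in percentage points became -12.4 for microglia-like, 10.4 for endothelial-like, 4.85 for neuroblast-like, -0.41 for ependymal-like and -4.02 for choroid plexus-like cells. With a limit of 20% they became -1.15 for astrocyte-like, 6.50 for endothelial-like and -5.71 for choroid plexus-like cells. With a relative UMI floor for the cKO library they became 10.3 for endothelial-like, 4.48 for neuroblast-like, 1.00 for oligodendrocyte-like and -0.014 for pericyte-like cells. The endothelial difference was 12.1 at Leiden resolution 0.5 and the neuroblast difference 0.811 with a floor of 2000 UMIs. With that floor the log2 ratio of Mgp in astrocyte-like cells was 0.71, and in microglia Gpnmb was -3.22, Cd74 -0.61 and the class II median -0.61. After thinning, Plxnb2 in astrocyte-like cells was -0.17, and in microglia Rap1b was -0.090, Pecam1 0.010, the cell cycle median -0.094 and the plexin median 0.24. The plexin median was 0.032 without doublet removal, 0.19 without the CPM floor and -0.10 in the microglia-marked union, and the cell cycle median was 0.62 without that floor and 3.43 in the union, which adds the cycling cluster 25 and has 11 measured members of that list. The plexin, class II and cell cycle lists have 3, 5 and 5 measured members in the named microglia class.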

Other observations

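Both observations below use values outside the main comparisons.

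Ttr, at 1542 CPM in control microglia and 1.25 CPM in cKO microglia, may be free RNA released from choroid plexus cells, of which the control library held 352 and the cKO library 4. One source would keep its genes in a fixed ratio, and control microglia had 69.7 Enpp2 UMIs per 1000 Ttr UMIs against 57.1 in control choroid plexus-like cells, a quotient of 1.22. That lies within the 2-fold bound set before the ratio was computed. The ratio was computed in microglia alone, and in the cKO library endothelial-like cells had 67.7 CPM of Enpp2 with 0.907 CPM of Ttr. Barcodes with 1 to 100 UMIs of the cKO library held Ttr at 1569 CPM (6146 UMIs) next to hepatocyte transcripts that kept cells of that library nearly lack, against 1.25 CPM of Ttr in its microglia. Alb stood at 3529 CPM in those smallest barcodes. In a group of larger cKO barcodes that stayed under 500 UMIs, Ttr was 23.6 CPM and Alb 16.7 CPM. In cKO barcodes with at least 500 but under 1000 UMIs, Ttr was 11.3 CPM and Alb 8.46 CPM. The Ttr level of 1569 CPM thus does not describe these larger barcodes. Where the Ttr and hepatocyte RNA of the smallest barcodes came from was not tested.

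The unnamed cycling cluster with microglial markers, and with Cdkn2a of the tumour naming set among its top genes, held 51 cKO and 2 control cells. In its cKO cells Mki67 stood at 876 CPM and Cdkn1a at 1224 CPM. Each had a UMI in 84.3% of those cells without thinning, at a median depth of 8825 UMIs. Transcripts of cycling cells and of this cell cycle inhibitor thus occurred in 1 cluster.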
